A study of Mus musculus with 3 samples.

How the data were processed

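Ribosome-depleted total RNA sequencing of the cytosolic fraction of mouse bone marrow-derived macrophages was analysed in 3 libraries. The labels give them as biological replicates 1, 2 and 3 of C57BL/6J cells at 0 minutes of a stimulation with 100 ng/ml lipid A, the part of bacterial lipopolysaccharide that activates the receptor TLR4. Each library has its own biosample in the labels, and all 3 carry the same donor label. Nothing in the labels separates cultures from animals, so SDs measure only the spread between these 3 samples, which may be technical. The p-values come from relabelling or resampling genes, so they do not measure the spread between samples. The labels also give 1 µg of starting RNA and a size range of 250 to 400, with no unit.

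Each library came with 3 tables. Per the file headers, the gene table and the first transcript table have the columns that RSEM writes, and the second transcript table has the columns that kallisto writes; tool versions were not given in the sources used here. Per the labels and the notes deposited with each library, the values refer to the mm10 assembly and the GENCODE M21 annotation, and the 3 libraries were made from 8, 10 and 10 read files. The authors deposited expected counts, which are estimated reads per gene or transcript and need not be whole. The authors also deposited TPM (transcript abundance scaled to the same total in each library over all genes), as a maximum likelihood and as a posterior mean estimate. FPKM (fragments scaled by effective length and library size) was deposited beside it, per the file headers. The share of a gene's transcripts taken by each isoform was deposited as a percent, per the file headers, and was recomputed here from TPM.

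Gene names, gene classes and coordinates came from the GENCODE M21 annotation of mm10, to which all 55536 gene identifiers in the tables matched. Of the transcripts in the RSEM-format transcript tables, 141862 matched the annotation, and 141767 of these were also present in the kallisto-format tables. The tables also list 26248 tRNA entries, 96 ERCC spike-ins and 1 phiX sequence, which stayed out of gene totals, shares and tests. The tRNA entries held 1, 2 and 2 counts in replicates 1, 2 and 3, and the ERCC entries held 0 counts in each. The phiX share is given among the additional observations. An effective length of 0, which leaves a short gene without a TPM, was listed for 4687 genes in all 3 libraries.

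Expected counts over genes summed to 26318761, 41897257 and 56290298 in replicates 1, 2 and 3. A gene with 0 counts could still have held up to 3 counts, or 0.114, 0.0716 and 0.0533 CPM (counts scaled to library size) in the same order. Confidence intervals of shares are 95% Wilson intervals. Intervals and floors cover counting error only.

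Gene lists, tests, thresholds and alternative settings were fixed before the data were examined, except where the text says otherwise. There is 1 group, so no comparison between treatments was possible, and an exact sign-flip test over 3 libraries cannot give a p below 0.25. Comparisons were therefore made between gene lists within the libraries, and between each library and the other two. A gene counted as detected at a TPM of at least 1. The median of log2(TPM + 1) over the members of a list was compared between lists by a two-sided permutation test with 100000 relabellings of the members, and adjusted by the Benjamini-Hochberg method within each family of comparisons. Genes of a list are not independent replicates, so these p-values describe the lists and not a population of animals. The level of each of 33 fixed lists, 11 of them for cell lineages, was placed among 10000 random lists of equal size drawn from genes of the same kind with a TPM of at least 1 in any library. A list below the 2.5 or above the 97.5 percentile was called below or above the random range.

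The spread between libraries was estimated with edgeR on expected counts rounded to whole numbers, with TMM scaling, edgeR's filter on low counts and a design with an intercept only. TMM factors were 1.04, 0.992 and 0.971 in replicates 1, 2 and 3. The SD of each gene's TMM log2 CPM (prior count 2) over the 3 libraries was summarised as a median per list. Its percentile among 10000 random lists matched on mean level in 20 bins gave a two-sided resampling p, adjusted over 26 lists with at least 3 members past the filter. The difference of each library from the mean of the other two was tested in the same way and adjusted over lists and libraries; this second test was added after the data were examined. The smallest p that the random lists can give is 0.0002, and the smallest that the relabellings can give is 1e-05. Co-regulated genes vary together more than random genes do, so these p-values state how unusual a list is among genes, not among cultures.

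The named genes were chosen by a rule. It takes the 10 protein-coding genes outside the mitochondrial genome and the 5 other genes with the highest mean TPM, the 3 highest members of each list, and list members below a TPM of 1 in every library. It also takes a set of macrophage, lipid A response and noncoding RNA genes named in advance. The 5 genes in each direction that differed most between both quantifications were taken too. So were the 10 genes with the largest SD of log2 CPM between libraries. These 10 were chosen among genes with a mean TPM of at least 10, past the filter on low counts and outside the mitochondrial genome. Where more than 3 members of a list were below a TPM of 1, they were counted and 2 of them named in alphabetical order. Values are means ± SD over the 3 libraries unless stated. Genes with near-identical copies or with an overlapping neighbour share reads, so their values are uncertain; this holds for the 7SL genes, small nuclear RNA copies, Rmrp, the ferritin and ribosomal protein genes with pseudogenes, globin and heat shock gene pairs, mitochondrial genes with nuclear copies, and Gm49369.

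Alternatives were leaving out each replicate in turn, kallisto-format TPM, FPKM, posterior mean TPM, TPM rescaled without mitochondrial and short noncoding genes, a pseudocount of 0.1, other minimum values, means in place of medians, DESeq2 size factors, DESeq2 dispersions, a prior count of 0.5 and 50 bins. An alternative scale for the comparison of quantifications, and kallisto-format TPM rescaled without 5 genes, were chosen after seeing the data.

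The steps were tested on simulated data. For the spread between 3 libraries, a coefficient of variation of 0.15 was recovered as 0.161 over 12920 genes. Lists of 25 genes changed in 1 library by 1.2, 1.5, 2 and 4 fold were recovered at 1.23, 1.48, 1.80 and 3.90 fold, with 2 of 2 lists called at each size by the library test; the spread test called 0 of 2 at 1.2 fold and 2 of 2 at the larger sizes. Among 20 unchanged lists of 25 genes, 0 were called. The simulated genes varied independently of one another, so this does not give the rate of calls for co-regulated or smaller lists. For the permutation test between lists of 20 and 10 genes, 5% of 200 simulations without a difference gave a p under 0.05, and a shift of 3 log2 units was recovered as 2.94 and called in 98.5%.

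Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.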

Results

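The series holds 1 group of 3 libraries from the cytosolic fraction of bone marrow-derived macrophages, taken at 0 minutes of a lipid A stimulation. No other time point or fraction was used here, so the data describe the cytosolic transcriptome at 0 minutes and its spread between libraries. Expected counts assigned to genes came to 26318761 in replicate 1, 41897257 in replicate 2 and 56290298 in replicate 3. All coordinates are on mm10, and all levels are TPM as mean ± SD (n = 3) unless another unit is named.

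Outside the mitochondrial genome, the most abundant mRNAs mostly encoded iron storage, lysosomal and secreted macrophage proteins. Ferritin light chain Ftl1 (chromosome 7, 45457944 to 45459884) reached 7726 ± 626 and ferritin heavy chain Fth1 (chromosome 19, 9980598 to 9985098) reached 6817 ± 1055. Psap (chromosome 10, 60277627 to 60302597), the precursor of lysosomal saposins, stood at 4805 ± 354, and the lysozyme gene Lyz2 (chromosome 10, 117277331 to 117282321) at 4792 ± 1020. Next came the lysosomal protease genes Ctsd (3888 ± 267) and Ctsb (2434 ± 262), Selenop for a secreted selenoprotein (2662 ± 491), Gpnmb (2382 ± 88.8), Apoe for apolipoprotein E (1900 ± 282) and cytoplasmic actin Actb (1756 ± 239). The 18 lysosomal genes on the fixed list took 7.27 ± 0.356% of all counts and both ferritin genes took 2.03 ± 0.210%.

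A TPM of at least 1 was reached by 9894, 9681 and 9870 genes in replicates 1, 2 and 3, and by 9461 of 55536 annotated genes in all 3 libraries. Protein-coding genes made up 9023 of these, out of 22028 annotated. Long intergenic noncoding RNA (lincRNA) genes made up 60 of 5854, antisense genes 47 of 2959 and pseudogenes 183 of 13525. Small RNA genes are undercounted here because an effective length of 0 was listed for 4687 genes. Requiring a TPM of 5 left 5458 genes detected in all 3 libraries. Protein-coding genes took only 23.3 ± 2.55% of TPM, against 61.5 ± 1.73% for the noncoding 7SL RNA, so mRNAs have low TPM values on this scale. A TPM below 1 therefore does not by itself mean an absence of reads. The 7 mast cell and basophil genes on the fixed list, each below 1 in every library, together held 117 counts in replicate 1.

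The libraries resembled one another across genes, with a Pearson r of log2(TPM + 1) of 0.994 between replicates 1 and 2, 0.992 between 1 and 3 and 0.993 between 2 and 3; genes are not independent replicates. The counts of each pair differed by far more than sampling noise, with a chi-square per degree of freedom of 44.3, 70.6 and 54.7 in the same order. This sets aside counting noise alone, and does not tell separate cultures from separate preparations of 1 RNA sample. The common biological coefficient of variation was 0.145 over 12413 genes. It was 0.163 without replicate 1, 0.161 without replicate 2 and 0.109 without replicate 3. The median gene had an SD of 0.12 log2 units between libraries.

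The first comparison asked whether the preparation carried transcripts of macrophages rather than of other marrow lineages. All 20 macrophage identity genes were detected in all 3 libraries, with a median level of 228. Lyz2, the galectin gene Lgals3 (1341 ± 150) and the protease gene Ctss (865 ± 139) led the list. The receptor gene for colony stimulating factor 1, Csf1r (chromosome 18, 61100598 to 61132149), stood at 254 ± 32.6, the F4/80 antigen gene Adgre1 at 153 ± 21.5, the lysosomal membrane glycoprotein gene Cd68 at 663 ± 66.5 and the integrin gene Itgam at 22.0 ± 1.27.

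Most markers of the 10 other lineages were below a TPM of 1, which by itself is not an absence of reads. Neutrophil granule genes were below a TPM of 1 in every library for 8 of 12 members, among them Camp and Cxcr2, while the calprotectin genes S100a9 (10.8 ± 0.307) and S100a8 (6.29 ± 0.295) and the collagenase gene Mmp8 (4.71 ± 0.826) were detected. T cell genes were below 1 in every library for 9 of 10 members, including Cd3d and Cd3e; the exception was Cd4 (20.5 ± 0.506), followed by Lat (0.303 ± 0.0702) and Lck (0.0367 ± 0.0321). B cell genes were below 1 for 9 of 10, including Cd79a; the immunoglobulin gene Ighm stood at 4.20 ± 0.762, Cd79b at 0.713 ± 0.137 and Igkc at 0.460 ± 0.151. All 7 natural killer cell genes were below 1, among them Eomes and Gzma, and the 3 highest were Klrd1 (0.0933 ± 0.0569), Nkg7 (0.0100 ± 0.0173) and Klrb1c (0.00333 ± 0.00577). Erythroid genes were below 1 for 9 of 10, with Car1 and the globin gene Hba-a1 at 0, and the erythropoietin receptor gene Epor stood at 1.69 ± 0.323, ahead of Alas2 (0.11, 0.04 and 0.15 in replicates 1, 2 and 3) and Hba-a2 (0.0233 ± 0.0404).

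Megakaryocyte and platelet genes were below 1 for 6 of 7, including Gp1ba (0.113 ± 0.0252) and Gp6, with Ppbp at 0.677 ± 0.115, but the platelet factor 4 chemokine gene Pf4 reached 170 ± 17.5. All 7 mast cell and basophil genes were below 1, among them Cpa3 (0.0600 ± 0.0361) and Fcer1a, with Kit highest at 0.510 ± 0.193. Dendritic cell genes were below 1 for 7 of 8, including Ccr7 (0.357 ± 0.0757) and Cd209a; the integrin gene Itgax stood at 1.35 ± 0.196 and Siglech at 0.217 ± 0.0586. Osteoclast genes were below 1 for 5 of 8, including Calcr and Dcstamp, and the transcription factor gene Nfatc1 stood at 11.9 ± 1.67, the acid phosphatase gene Acp5 at 1.06 ± 0.271 and the protease gene Ctsk at 1.06 ± 0.116. All 9 fibroblast genes were below 1, with the collagen genes Col1a1 and Col1a2 at 0.0333 ± 0.0208 and 0.0367 ± 0.0208.

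The median macrophage gene exceeded the median of each other list by 7.50 to 7.82 log2(TPM + 1) units. The difference was 7.50 ± 0.22 against the neutrophil list (adjusted permutation p = 5e-05) and 7.67 ± 0.19 against the dendritic cell list (adjusted permutation p = 0.00015). The difference was 7.82 ± 0.22 against the natural killer cell list, which had the highest of the 10 adjusted permutation p-values, 0.0011. It was positive in each of the 3 libraries for all 10 lists.

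**Figure D1:**
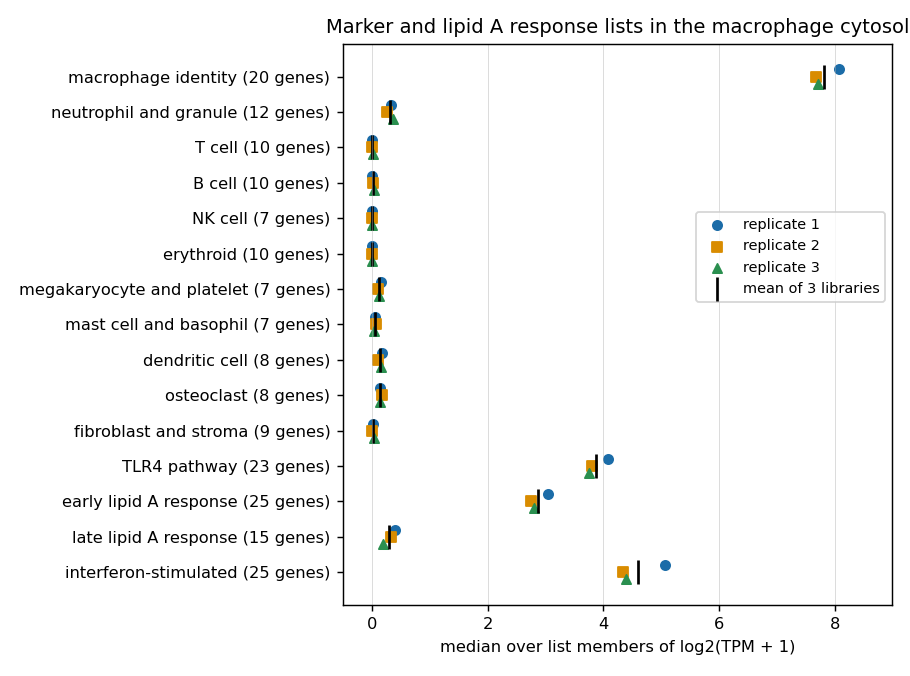
Median log2(TPM + 1) over the members of each marker and lipid A response list, with 1 symbol per library and a bar for the mean of the 3 libraries. The macrophage list sits at a mean of 7.82, and the other 10 lineage lists sit at 0.32 or lower.

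The next comparison set the genes that sense lipid A against those that lipid A induces, to describe the state from which a response would start. All 23 genes of the TLR4 pathway were detected in all 3 libraries. The co-receptor gene Cd14 stood at 39.8 ± 4.06, the transcription factor gene Irf5 at 32.4 ± 4.25, the receptor gene Tlr4 (chromosome 4, 66827584 to 66930284) at 29.0 ± 4.53, its partner Ly96 (MD-2) at 14.6 ± 3.35 and the adaptor gene Myd88 at 18.1 ± 3.87. Genes of the late response were mostly low, with 9 of 15 below a TPM of 1 in every library, among them Csf2 (0.0133 ± 0.0115) and Csf3 (0.00333 ± 0.00577). The interleukin gene Il6 had 1, 4 and 3 counts in replicates 1, 2 and 3, whereas the chemokine gene Ccl5 reached 28.5 ± 5.14, the serum amyloid gene Saa3 14.8 ± 3.26 and the itaconate-producing enzyme gene Acod1 3.93 ± 1.42.

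Early response genes lay between, with 22 of 25 detected in all 3 libraries. The chemokine genes Ccl3 (76.9 ± 9.79) and Ccl4 (53.7 ± 6.97) and the transcription factor gene Atf3 (74.7 ± 5.05) were highest. Other early genes were lower, with the NF-kB inhibitor gene Nfkbia at 13.0 ± 4.32, the immediate early genes Fos at 10.2 ± 2.62 and Egr1 at 6.10 ± 1.07, and the cytokine genes Tnf at 5.59 ± 0.906 and Il1b at 2.21 ± 0.952. The chemokine gene Cxcl1 (0.213 ± 0.146) and the prostaglandin synthase gene Ptgs2 (0.197 ± 0.0709) were below 1 in every library. All 25 interferon-stimulated genes were detected in all 3 libraries. Bst2 for the antiviral protein tetherin (120 ± 50.3) and the antiviral genes Ifit2 (89.8 ± 49.9) and Ifit3 (80.2 ± 36.3) were highest, and Irf7 stood at 55.0 ± 22.0, Isg15 at 31.7 ± 17.4, Ifit1 at 20.2 ± 10.1 and Cxcl10 at 11.1 ± 10.1.

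The median of the TLR4 pathway list lay 3.57 ± 0.10 log2 units above the late response list (adjusted permutation p = 6e-05) and 1.01 ± 0.06 above the early response list (adjusted permutation p = 0.0445). The early difference lost its call when any 1 library was left out, at adjusted permutation p-values of 0.0760, 0.0991 and 0.0509 without replicates 1, 2 and 3, and fell to 0.46 log2 units when members below a TPM of 1 were left out. The difference from the interferon-stimulated list was -0.72 ± 0.23 (adjusted permutation p = 0.144), and a mean over members in place of the median gave -0.93 (adjusted permutation p = 0.0162).

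Among genes of macrophage function, those for receptors that bind antibody and debris were high. All 6 Fc receptor genes were detected in all 3 libraries, led by the common signalling chain Fcer1g (527 ± 78.1), Fcgr3 (203 ± 41.9) and the inhibitory receptor gene Fcgr2b (148 ± 27.4). Scavenger receptor genes were detected in all 3 libraries for 6 of 9, led by Stab1 (157 ± 13.1), Cd36 (114 ± 35.5) and the mannose receptor gene Mrc1 (111 ± 6.22), while Cd163 (0.660 ± 0.0656) and Olr1 (0.0667 ± 0.0551) were below 1. Toll-like receptor genes were detected in all 3 libraries for 9 of 12, led by Tlr7 (65.0 ± 10.7), Tlr13 (59.7 ± 5.41) and Tlr8 (54.7 ± 9.98), which sense RNA in endosomes, and Tlr5, Tlr11 and Tlr12 were below 1. Most alternative activation genes were low: 8 of 12 were below 1, including the arginase gene Arg1, with 2, 0 and 7 counts in replicates 1, 2 and 3, and Ccl17. Retnla had 0 counts in every library, which allows up to 3 counts in each, while Mrc1, Il4ra (21.5 ± 2.74) and Clec10a (10.8 ± 3.06) were highest on that list.

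All 11 genes of the NF-kB and IkB family were detected in all 3 libraries, led by Rela (16.4 ± 2.24), Nfkb1 (16.4 ± 2.40) and Nfkbia. Interferon regulatory factor genes were detected in all 3 libraries for 7 of 9, led by Irf7, Irf8 (51.1 ± 7.96) and Irf5; Irf4 (0.520 ± 0.130) was below 1. All 10 genes on the list named AU-rich element binding were detected, led by Zfp36l1 (44.2 ± 5.77), Zfp36l2 (40.3 ± 3.53) and Hnrnpd (30.3 ± 3.95). AU-rich elements control the decay of cytokine mRNAs, and binding to them was not checked for each listed protein.

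Among the cell biology lists, all 18 lysosomal genes were detected in all 3 libraries with a median of 339, and all 14 glycolysis genes with a median of 63.0, led by Gapdh (282 ± 44.4), Aldoa (157 ± 21.3) and Pkm (111 ± 5.33). All 18 cholesterol synthesis genes were detected in all 3 libraries, led by Msmo1 (44.5 ± 8.22), Hmgcs1 (34.7 ± 5.04) and the regulator gene Srebf2 (24.6 ± 3.16). Cell cycle genes were low, with a median of 1.89 and the mitotic kinase gene Bub1 (0.667 ± 0.0764) below 1 in every library; the replication clamp gene Pcna (62.3 ± 2.32) stood far above Mcm6 (8.68 ± 0.132) and Mcm3 (6.09 ± 0.641). Stress genes were led by the chaperone genes Hspa8 (373 ± 84.3) and Hspa5 (169 ± 32.1) and by Txnip (107 ± 9.94), and the inducible heat shock genes Hspa1a (0.787 ± 0.0751) and Hspa1b (0.280 ± 0.0600) were below 1. All 12 housekeeping genes were detected, led by Actb, B2m (1733 ± 420) and Eef1a1 (1466 ± 243).

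Against random lists of equal size drawn from genes with a TPM of at least 1, 13 of the 33 lists lay above the random range and 15 below it. The lists above were macrophage identity, TLR4 pathway, interferon-stimulated, AU-rich element binding, Fc receptors, scavenger receptors, lysosome, glycolysis, heat shock and stress, housekeeping, mitochondrial mRNA, and cytoplasmic and small structured noncoding RNA, and each of these also lay above when random genes needed only a nonzero TPM. With kallisto-format TPM, the TLR4 pathway (95.8), AU-rich element binding (96.3) and cytoplasmic noncoding RNA (97.3) lay within the range, and the last of these also did without replicate 1 (94.6) and without replicate 3 (97.4). A position below the range is partly built in, because the lists keep undetected members and the random genes do not include any. With the nonzero background, 11 lists stayed below: 9 of the other lineages, late lipid A response, and X inactivation and Y-linked genes. There the nuclear-retained noncoding RNA list turned from percentile 0 to 99.9, and megakaryocyte and platelet (4.97), alternative activation (5.10) and cell cycle (26.3) lay within the range. Early lipid A response lay at the 36.9 percentile of detected genes and at 93.9 with the nonzero background (7.72 with kallisto-format TPM), and the NF-kB and IkB family at 57.6 and 91.5. Toll-like receptors (85.3), cholesterol synthesis (88.1) and interferon regulatory factors (97.0) lay within the range of detected genes and above the range with the nonzero background; the last of these also lay just above the range without replicate 2. With members below a TPM of 1 left out, 3 lists lay below the range: osteoclast, late lipid A response and cell cycle.

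Protein-coding genes took 85.1 ± 2.54% of the expected counts, with 88.0, 83.9 and 83.4% in replicates 1, 2 and 3. The 7SL RNA of the signal recognition particle, which guides secretory proteins to the endoplasmic reticulum, took 10.7 ± 1.37%, and the short 7SL genes Rn7s2 (chromosome 12, 69361182 to 69361481) and Rn7s1 (chromosome 12, 69159295 to 69159594) stood at 309194 ± 9425 and 305430 ± 7904 TPM. The 7SK RNA Rn7sk, a regulator of transcription elongation, took 1.63 ± 0.659% of counts, with 0.894, 1.84 and 2.16% in replicates 1, 2 and 3. The RNA subunits of RNase P (Rpph1, 41019 ± 6136) and RNase MRP (Rmrp, 15178 ± 4671 at the higher of its annotated genes) followed. The vault RNA Vaultrc5 stood at 94.8 ± 18.8 and the telomerase RNA Terc at 1.82 ± 1.12.

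The Y RNA genes Rny1 and Rny3 were listed at 0 with an effective length of 0, and the kallisto-format tables gave them 4.72 ± 1.82 and 29.9 ± 8.04, so they cannot be called absent. The 354 genes that the annotation types as ribosomal RNA held 0.0210 ± 0.00870% of counts. This share covers those genes alone and does not measure how complete the ribosome depletion was. Messenger RNAs for ribosomal proteins held 2.12, 1.98 and 1.55% in replicates 1, 2 and 3, and mitochondrial mRNAs held 0.709 ± 0.286%. The mitochondrial share leaves out reads that were assigned to nuclear copies of mitochondrial genes. The unit set the picture: protein-coding genes took 23.3 ± 2.55% of TPM and 7SL 61.5 ± 1.73%, against 10.3 ± 1.23% and 21.7 ± 3.71% of kallisto-format TPM. Of the kallisto-format TPM, 62.5 ± 5.24% went to 5 genes listed at 0 in the gene tables, which leaves less of the total for other genes.

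**Figure D2:**
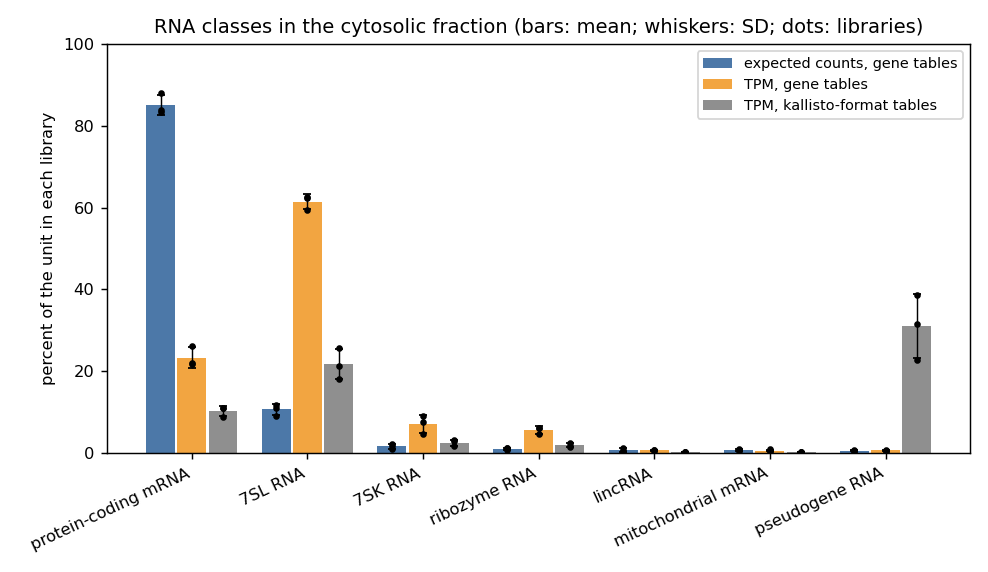
Percent of each library in 7 RNA classes, by expected counts, by gene table TPM and by kallisto-format TPM; bars are means, whiskers are SDs and dots are the 3 libraries, and mitochondrial mRNA is also part of the protein-coding class. Protein-coding mRNA holds 85.1% of counts and 23.3% of TPM, while 7SL RNA holds 10.7% of counts and 61.5% of TPM.

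Because the material was a cytosolic fraction, noncoding RNAs known to stay in the nucleus were set against those known to be exported. Exported noncoding RNAs were present at moderate levels, with 9 of 11 measured members detected in all 3 libraries, led by 2900097C17Rik (60.4 ± 6.34), Gas5 (33.1 ± 5.10) and Zfas1 (9.61 ± 2.30); Dancr (0.297 ± 0.122) and H19 (0.0267 ± 0.0379) were below 1. Of the nuclear-retained RNAs, 8 of 12 were below 1 in every library, including Airn (0.347 ± 0.131) and Ftx (0.327 ± 0.0569). The exceptions were Malat1 (chromosome 19, 5795690 to 5802672), a nuclear speckle RNA, at 479 ± 458, the paraspeckle RNA Neat1 (chromosome 19, 5824708 to 5845478) at 42.6 ± 43.2, Xist, the RNA that coats the inactive X chromosome, at 4.63 ± 4.83, and Firre at 1.91 ± 1.43. The exported list lay 2.83 ± 0.36 log2 units above the nuclear list (adjusted permutation p = 0.0437). The direction turned, to -0.28 (adjusted permutation p = 0.783), when members below a TPM of 1 were left out. The mean over members gave 1.21 (adjusted permutation p = 0.220). The difference therefore rests on RNAs with a TPM below 1. A low TPM did not always mean few reads, since 8 of the 12 nuclear-retained RNAs passed the filter on low counts.

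The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were at a TPM of 0 in all 3 libraries, and Ddx3y had 0 counts, which allows up to 3 counts per library. Xist stood at 2.79, 0.98 and 10.1 in replicates 1, 2 and 3.

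The last comparisons asked which gene groups differed between the 3 libraries by more than genes of the same level; the test of single libraries was added after the data were examined. Interferon-stimulated genes were higher in replicate 1 for 25 of 25 members, by a median of 0.68 log2 units (1.60-fold over the other two, adjusted p = 0.000918 from random-list resampling). Cxcl10 had 22.8, 5.81 and 4.75 TPM in replicates 1, 2 and 3, Isg15 had 51.8, 21.9 and 21.5, and Ifit1 had 31.8, 14.6 and 14.1. Cholesterol synthesis genes were higher in replicate 2 for 18 of 18 members, by a median of 0.56 (1.48-fold, adjusted p = 0.000918), with the farnesyl diphosphate synthase gene Fdps at 19.5, 24.9 and 12.3 TPM. Cell cycle genes were also higher in replicate 2 for 18 of 18 members, by 0.42 (1.34-fold, adjusted p = 0.000918), with Mki67 at 3.10, 4.39 and 3.66 TPM. The same list was about as far down in replicate 1, at -0.40 with 0 of 18 members higher (adjusted p = 0.000918), and replicate 3 lay at 0.08. The 3 differences of each gene sum to 0, so a shift in 1 library brings opposite values in the others, and calls in several libraries for the same list are not separate results.

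Nuclear-retained noncoding RNAs were higher in replicate 3 for 8 of 8 members tested, by a median of 2.11 log2 units (4.33-fold, adjusted p = 0.000918). Malat1 had 224, 207 and 1008 TPM in replicates 1, 2 and 3, and Neat1 had 18.7, 16.7 and 92.5. Mitochondrial mRNAs were higher in replicate 3 for 11 of 13 members, by 1.04 (2.05-fold, adjusted p = 0.000918), and lower in replicate 1, at -0.90 (adjusted p = 0.000918). The mitochondrial list was led by mt-Atp8 (2204 ± 848), mt-Co1 (1196 ± 426) and mt-Nd1 (435 ± 177), while mt-Co2 and mt-Co3 had their lowest TPM in replicate 3, at 12.6 and 88.0. Mitochondrial genes with nuclear copies share reads with them, so the levels of single genes on this list are uncertain. Small nuclear RNA genes held 0.00994, 0.0121 and 0.0376% of counts in replicates 1, 2 and 3, and sense-intronic genes held 0.00516, 0.00427 and 0.00866%.

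**Figure D3:**
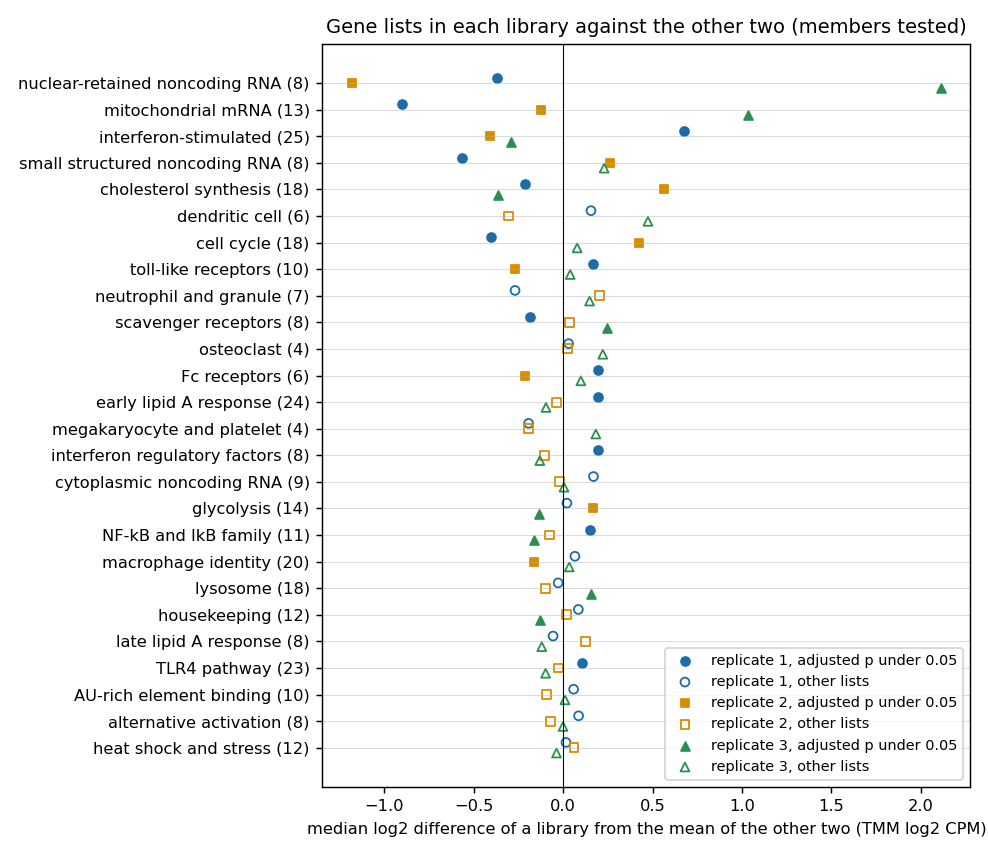
Median log2 difference of each library from the mean of the other two for 26 gene lists, on TMM log2 CPM, with filled symbols for an adjusted p under 0.05; the number of members tested is in brackets. Nuclear-retained noncoding RNA in replicate 3 lies at 2.11, mitochondrial mRNA in replicate 3 at 1.04 and interferon-stimulated genes in replicate 1 at 0.68.

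Further differences passed the same test in other lists. In replicate 1, the medians were 0.20 for early lipid A response (19 of 24 members higher), 0.19 for interferon regulatory factors, 0.20 for Fc receptors, 0.17 for toll-like receptors, 0.15 for NF-kB and IkB family and 0.10 for the TLR4 pathway, and they were -0.57 for small structured noncoding RNA and -0.19 for scavenger receptors, each with 1 of 8 members higher. The shift of the early lipid A list fell to 0.07 (adjusted p = 0.383) when limited to members with a mean TPM of at least 10, and the late list showed no call in replicate 1, at -0.06. In replicate 2, glycolysis genes were higher by 0.17 in 14 of 14 members and small structured noncoding RNA by 0.26, while macrophage identity genes lay at -0.16, Fc receptor genes at -0.21 and toll-like receptor genes at -0.27. In replicate 3, lysosomal genes were higher by 0.16 in 14 of 18 members and scavenger receptor genes by 0.25 in 5 of 8, while NF-kB and IkB family genes lay at -0.16, glycolysis genes at -0.14 and housekeeping genes at -0.13. Among members with a mean TPM of at least 10, the call also ended in replicate 1 for the TLR4 pathway (adjusted p = 0.0922), toll-like receptors (0.0704) and the NF-kB and IkB family (0.131), and in replicate 3 for the last of these (0.131). The shifts themselves hardly moved, at 0.11, 0.17, 0.15 and -0.16 in that order, while the 3 lists kept only 12, 6 and 4 members.

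By the spread over all 3 libraries, 10 of 26 lists exceeded random lists of the same level. The median SD was 1.22 log2 units for nuclear-retained noncoding RNA, 0.65 for mitochondrial mRNA, 0.41 for interferon-stimulated genes and 0.34 for cholesterol synthesis, each with an adjusted p of 0.00104, as for early lipid A response (0.20). It was 0.28 for cell cycle (adjusted p = 0.0026), 0.34 for small structured noncoding RNA (0.0111), 0.20 for the NF-kB and IkB family (0.0117), 0.16 for macrophage identity (0.0156) and 0.18 for toll-like receptors (0.0452). Of these 10 calls, 5 were lost by leaving out 1 particular library: the interferon-stimulated list had an adjusted p of 0.635 without replicate 1, small structured noncoding RNA 0.388 without replicate 1, cholesterol synthesis 0.859 and cell cycle 0.262 without replicate 2, and the nuclear-retained list 0.871 without replicate 3. Another 4 were lost by leaving out either of 2 libraries. Without replicates 1 and 2 in turn, the adjusted p was 0.796 and 0.454 for early lipid A response, 0.635 and 0.465 for toll-like receptors, and 0.0979 and 0.391 for macrophage identity. For the NF-kB and IkB family it was 0.796 without replicate 1 and 0.271 without replicate 3. The mitochondrial list was the one of the 10 that passed with each library left out. Small structured noncoding RNA also lost its call with 50 bins (adjusted p = 0.0536). Among members with a mean TPM of at least 10, so did early lipid A response (0.127), toll-like receptors (0.188), the NF-kB and IkB family (0.765) and small structured noncoding RNA (0.0691), and the nuclear-retained and cell cycle lists had too few members for a value. The median SD of the first 3 of these was then 0.14, 0.16 and 0.10, over 12, 6 and 4 members, so that of toll-like receptors changed little. The number of lists past the threshold was 4, 6 and 8 without replicates 1, 2 and 3. The 6 include AU-rich element binding, whose median SD was then lower than in random lists, at 0.02 against 0.09 (adjusted p = 0.0312).

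Single genes with the largest SD of log2 CPM between libraries, by the rule given above, were Gm49369, Malat1, Gm20721, Gm23444, Gm23472, Neat1, Gm26917, Gm22614, Gm25890 and Snord17. A gene outside this ranking can vary widely in TPM, as did the small nucleolar RNA gene Snord22, at 234 ± 405. Gm49369 (chromosome 7, 142371096 to 142382667) had 117, 787 and 536 TPM in replicates 1, 2 and 3, and overlaps Ctsd (chromosome 7, 142375911 to 142388038) on the same strand, so its level is uncertain. Gm20721, which lies opposite the Gnas gene, had 3.29, 23.5 and 10.3 TPM. The small nuclear RNA genes Gm23444 and Gm23472 had identical values of 248, 223 and 1077, as did Gm22614 and Gm25890, at 119, 153 and 483, so reads within each pair were not told apart. The lincRNA gene Gm26917 had 55.1, 14.9 and 107 TPM, and the small nucleolar RNA gene Snord17, within Snx5, had 6.67, 4.18 and 22.6.

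Leading transcripts took from nearly all to little over 50% of the named macrophage genes. Among 3302 protein-coding genes with several transcripts and a mean TPM of at least 10, 83.8 ± 0.809% gave at least 50% of their TPM to a single leading transcript, a limit that any gene with 2 transcripts meets. Fth1-201 took 99.0 ± 0.232% of Fth1 and Cd68-201 took 98.2 ± 0.354% of Cd68. Tlr4-201 took 98.5 ± 0.439% of Tlr4 and Myd88-201 took 99.4 ± 0.322% of Myd88. Shares were lower for Psap-202 (57.0 ± 3.06% of Psap), Apoe-209 (66.7 ± 5.27% of Apoe) and Irf7-201 (53.5 ± 4.24% of Irf7). For Ctsd, Ctsd-202 took 64.2 ± 4.14%, against 98.9 ± 0.652% in the kallisto-format tables, and for Csf1r the leading transcript was Csf1r-202 (66.9 ± 11.0%), against Csf1r-201 (62.5 ± 5.38%) there. Transcripts annotated as retained introns took 2.88, 2.81 and 3.55% of the TPM of protein-coding genes in replicates 1, 2 and 3.

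The 2 quantifications of each library were compared gene by gene. Across genes, Pearson r of log2(TPM + 1) was 0.966, 0.967 and 0.953 in replicates 1, 2 and 3, and Spearman rho was 0.861, 0.855 and 0.816. Of the kallisto-format gene TPM, 62.5 ± 5.24% went to 5 genes that were listed at 0 in the other quantification. TPM has a fixed total, so this lowers the kallisto-format values of all other genes. The kallisto-format TPM of the median gene was 0.436 times the gene table TPM, and 3237 of 3725 genes differed by over 2-fold. With both files brought to the same median ratio, a scale chosen after seeing the data, 137 genes did. After that centring, the genes lowest in the kallisto-format tables were Gm49369, the ribosomal protein gene Rpl10 (517 ± 150 against 26.4 ± 6.68), the small nucleolar RNA genes Snord22 and Gm25776 and the small nuclear RNA gene Gm24407. The highest were Rps12-ps3 (21.5 ± 5.17 against 261 ± 72.1), Rpl10-ps3 (32.3 ± 4.68 against 212 ± 61.8), Rpl28-ps1, Gm10275 and mt-Atp6 (138 ± 26.1 against 333 ± 98.7). Several of these are copies of ribosomal protein genes, whose reads can be shared with the parent gene, so their values are uncertain in both files.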

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

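The tests of library depth and of short RNA retention, and both tests on interferon-stimulated genes, were chosen only after the result was seen. The tests on nuclear material and on 7SL RNA are recorded as written before. They are worded for patterns of these data, and those on nuclear material name replicate 3. At most their bounds were therefore set before the test values, and not the choice of pattern or library. Reads assigned to phiX, a bacteriophage genome used as a sequencing control, were found outside the measured genes: they made up 0.406% of expected counts in replicate 1 (95% Wilson interval 0.403 to 0.408), 0.121% in replicate 2 (0.120 to 0.122) and 0.0731% in replicate 3 (0.0724 to 0.0738). Each share lies above the limit that a count of 0 allows, and the libraries include no control sample.

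Nuclear-retained noncoding RNAs, led by Malat1 and Neat1, were 4.33-fold higher in replicate 3. Library depth alone is argued against by a median of -0.19 log2 units between replicates 2 and 1, whose depths also differ. A gain of short RNAs alone is argued against by length, since 7 of the 8 members have an effective length of at least 1000. Their median of 2.40 covers nearly the same genes as the 2.11 of the whole list, so it is no separate support. More nuclear material in this cytosolic preparation is a candidate explanation that remains: sense-intronic genes held 1.84 times the mean share of the other libraries, beyond the 1.21-fold between those, and retained-intron transcripts 1.25 times, beyond 1.03-fold. Mitochondrial mRNAs were also 2.05-fold higher in replicate 3, which nuclear material alone would not bring, and 7SK RNA was not set apart in that library in the same way, at 1.84% of counts in replicate 2 and 2.16% in replicate 3. The design names no difference between replicates, so no biological explanation was tested.

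All 25 interferon-stimulated genes were higher in replicate 1, by a median of 0.68 log2 units, against a range of -0.05 to 0.08 for matched random lists in that library. More cells of the 10 other listed lineages are argued against as the whole cause: the 25 genes gained 1756 CPM in replicate 1, and the largest rise of any lineage in markers with a low baseline, counting error added, was 0.0584% of that gain. A low baseline meant a TPM below 1 in replicates 2 and 3, with replicate 1 left out of the choice. Cell types outside those lists were not tested. Some activation of the lipid A type in replicate 1 may be involved, since the early lipid A list reached percentile 100 of random lists there, by 0.20 log2 units, although the shift was 0.07 among members with a mean TPM of at least 10 and the late list lay at -0.06. A source of interferon in replicate 1 also stays open. Beyond lipid A-type activation, no biological explanation was tested, because the design names no difference between replicates.

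The 7SL genes took 61.5% of TPM but 10.7% of counts. TPM divides by effective length, which was 81.9, 94.1 and 94.0 for Rn7s1 in replicates 1, 2 and 3 against an annotated length of 300. Dividing the counts by annotated length gave 43.1% (SD 2.44, n = 3). Annotated length alone thus took the share from 10.7 to 43.1%, and effective length in its place took it on to 61.5%. The value of 43.1% lies between the bounds of 40 and 50% recorded as set in advance, so that test gave no call on effective length as the cause. No biological explanation was tested, because a cytosolic fraction is all that the design holds.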

How the results depend on the processing

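The centred comparison of quantifications and 1 rescaled kallisto-format TPM were chosen after seeing the data. Of 198 alternative values for 25 main results, 171 stayed as reported, and all 92 for macrophage identity against other lineages did (5.14 to 11.14 log2 units), as did all 10 for TLR4 against late lipid A genes (2.18 to 5.39). A tested difference stayed if its call and, where called, its direction were kept, even where its size changed. Counts stayed if within a fixed fold of the main count, and other values if within 1 SD of the main value. With members below TPM 1 left out, 8 lineage lists kept too few genes for a value. The cause of the following changes was not tested unless fewer genes or libraries explain it. For genes detected, TPM of at least 5 gave 5458. Lowest replicate r, 0.992, was 0.988 with pseudocount 0.1, 0.974 for genes with TPM of at least 1 and 0.987 for kallisto-format TPM. The biological coefficient of variation was 0.193 without a filter on counts, 0.0630 from DESeq2 dispersions and 0.109 to 0.163 with 1 library left out. Protein-coding share was 23.3% of TPM and 10.3% of kallisto-format TPM, and 7SL share 61.5% and 21.7%. TLR4 over early lipid A genes lost its call with 1 library left out (0.99 to 1.04), without low members (0.46) and by means (0.50); by means, TLR4 against interferon-stimulated genes gained one (-0.93). Cytoplasmic over nuclear noncoding RNA reversed to -0.28 without low members and lost its call by means (1.21). Lists below the random range numbered 3 without low members. Lists past the spread threshold, in either direction, numbered 4 at a mean TPM of at least 10 and 4 to 8 with 1 library left out. Leading-transcript use was 88.0% at TPM 50. Genes over 2-fold apart between quantifications were 8321 at TPM 1, 682 at TPM 50 and 137 after centring. Among other results, 83 of 294 named gene values, 16 of 189 list levels, 19 of 174 list spreads and 5 of 123 single-library differences changed. The named gene values include FPKM and kallisto-format TPM set against TPM, which differ in scale. Depth limits statements on genes under 3 counts. No paired analysis was possible because there is 1 group.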

Other observations

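Tests in this part: none was run; the genes named here were chosen after their values were seen. Several list members stood apart from the rest of a low lineage list, and macrophages are known to transcribe some of them. Pf4 reached 170 ± 17.5 TPM (n = 3) while the other 6 platelet genes stayed below 1, and Cd4 reached 20.5 ± 0.506 while Cd3e, Cd8a and Trac were at 0. S100a9 and S100a8 stood at 10.8 ± 0.307 and 6.29 ± 0.295 with Mpo at 0.120 ± 0.0173 and Elane at 0.163 ± 0.0808. Among cell cycle genes, Pcna was at 62.3 ± 2.32 and Mki67 at 3.72 ± 0.647. The gene for the beta-glucan receptor, Clec7a, which the annotation types as a polymorphic pseudogene, stood at 122 ± 35.7.

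A block of pseudogenes on chromosome 1, annotated between 24612407 and 24616197, had high values: Gm28661 1130 ± 406, Gm28437 808 ± 333 and Gm10925 657 ± 275 TPM in the gene tables. The kallisto-format tables gave 446 ± 115, 205 ± 60.0 and 0.305 ± 0.0527. These pseudogenes were examined here as nuclear copies of mitochondrial genes, which share reads with those genes. Their values and those of the mitochondrial genes are therefore uncertain. High values do not show that the pseudogenes themselves are transcribed. Mitochondrial genes in the gene tables ranged from mt-Co2 at 18.1 ± 5.22 to mt-Atp8 at 2204 ± 848.

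In the kallisto-format tables, 5 genes that are listed at 0 in every gene table held 62.5 ± 5.24% of the gene TPM, with 63.5, 56.8 and 67.1% in replicates 1, 2 and 3. They are the processed pseudogenes Gm12896 (153741 ± 39533) and Gm12895 (153641 ± 39466) on chromosome 4 and the miRNA-type genes Gm23935, Gm24270 and Gm24245, at 105743 ± 9182 each. The first 2 are 226 bases long and the other 3 are 57 bases long, with an effective length of 0 in the gene tables.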
